A study of Arabidopsis thaliana with 13 samples.

How the data were processed

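Chromatin immunoprecipitation sequencing was done by the authors on whole seedlings of Arabidopsis thaliana, ecotype Columbia, in lines carrying a FLAG-tagged CRY2 (driven by the UBQ10 promoter), PIF4 or PIF5 transgene. Per the labels' protocols, seedlings were grown in white light for 5 days and then kept in low blue light for 16 h, and each protein was precipitated with an anti-FLAG antibody. The 13 libraries fell into 6 groups. CRY2 had 2 FLAG and 2 IgG libraries, PIF4 had 3 FLAG and 2 IgG libraries, and PIF5 had 2 FLAG and 2 IgG libraries. Per the labels' protocols, CRY2 was precipitated from 18 g of seedlings with a second cross-linker (ethylene glycol bis-succinimidylsuccinate), and the PIFs from 2 g without it.

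The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.1.0 and MACS2 2.0.10 and the genome build TAIR10, without stating the role or order of the tools. The deposited data analysed here were 3 peak lists, 1 per protein, in which the authors had pooled the replicates. In each list the authors gave the strength of a peak as a ratio, the fold enrichment of the FLAG precipitation over its control. They also gave the deposited -log10 p of the peak, and a deposited score equal to the whole part of 10 times that -log10 p in every line. The other deposited measures were the summit offset in bp and a constant in place of a q value, so no q value was used. The number of columns of per-sample values not used was 0. Read depth per library is not given in the sources used here, so no value could be scaled to depth, and no spread between replicates was available. Fold enrichment was compared within a list, since each list had its own IgG control. No anti-FLAG precipitation from untagged plants was used here.

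All steps used the 5 nuclear chromosomes and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Positions are peak coordinates on TAIR10, counted from 1. The gene table used was that of RefSeq, without strand and without sequence, for 27444 nuclear protein-coding genes. Its frame was checked by shifting it: the share of PIF4 summits outside genes but within 1 kb of one was 49.2% in place, and 20.7% after a shift of 2000 bp. A peak was assigned to the protein-coding gene nearest to its summit within 3 kb, and a gene with such a peak was called bound. Because the strand was not known, plans that named transcription start sites were replaced. The promoter share became the share of summits outside genes and within 1 kb of a gene edge, and random positions were matched on the distance to the nearest gene edge. The planned tests of G-box and PBE-box elements, to which PIF proteins bind, were left out because they need the genome sequence. Where a q value was planned for a stricter list, the upper 50% by fold enrichment was used.

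Peaks were shared when they overlapped by at least 1 bp. Overlap was tested against 1000 random placements over whole nuclear chromosomes with one-sided permutation tests, which cannot give a p below 0.001. Gene-body and flank shares were tested two-sided against 1000 uniform placements. Gene overlaps and gene lists were tested with Fisher's exact test, two-sided, with p-values floored at 1e-300 and adjusted by Benjamini-Hochberg over the 3 pairs of lists or over the 42 tests of 14 gene lists in 3 proteins. Medians and Spearman correlations across peaks were tested with 100000 permutations, two-sided, with 1e-05 as the smallest p possible. Intervals are 95% (Wilson for shares) and cover counting error only. Peaks and genes are not independent replicates, and the tests compare these lists rather than seedlings.

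The comparisons, the gene lists and the rule for named genes were set before the data were examined. The 14 tested gene lists and a list of the loci used in the transgenes held 264 memberships together. The rule took the 10 genes bound by all 3 proteins with the best mean rank of fold enrichment, the 5 genes with the strongest peak among those bound by 1 protein alone, the bound or unbound state of every list member, and values for up to 4 members per list in listed order, starting with those bound by most proteins. All 264 memberships were matched to the gene table. The list of transgene loci was described but not tested. Alternatives covered the overlap rule, stricter lists, lists of equal size, the placement of random peaks, the gene assignment, the background of genes and gene length. Gene-body shares, tests among genes bound by 1 of 2 proteins, backgrounds set by the third protein, the regression on gene length, gene counts from lists of equal size and non-coding gene counts were chosen after seeing the data.

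The steps were tested on simulated data. When 0, 5 or 30% of CRY2 peaks were moved onto PIF4 peaks among 7320, the excess recovered was -0.13, 4.79 and 29.6%, with 0, 10 and 10 of 10 runs at p below 0.05. The other simulated peaks were placed by the same rule as the random placements. These runs therefore checked the computation, and not whether that rule suits real peaks. Random lists of 15 genes passed in 7 of 100 runs, and lists with 12 bound members in 100 of 100. A shift of 0.1 in the fold enrichment of PIF5 peaks was found in 20 of 20 runs, and a shift of 0 in 0 of 20.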

Results

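The study asked whether cryptochromes, the blue-light receptors of plants, and PHYTOCHROME INTERACTING FACTORs, bHLH transcription factors that promote elongation, act together in weak blue light. The data were 3 lists of binding regions from seedlings kept in low blue light for 16 h, for the photoreceptor CRY2 and the transcription factors PIF4 and PIF5. The CRY2 list held 7320 peaks with a median width of 579 bp, the PIF4 list 9925 peaks (837 bp) and the PIF5 list 3767 peaks (818 bp). Median fold enrichment over control was 2.29 for CRY2 (range 1.51 to 7.87), 2.46 for PIF4 (1.65 to 5.50) and 2.40 for PIF5 (1.86 to 7.21). CRY2 was bound at 6062 of 27444 nuclear protein-coding genes (22.1%), PIF4 at 7896 (28.8%) and PIF5 at 3262 (11.9%). Replicates were pooled in each list, so no value below has a spread between replicates, and the depth of the libraries is unknown. Material and cross-linking differed between the CRY2 and PIF precipitations, so a difference between CRY2 and a PIF is also one between protocols.

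The comparison of CRY2 with PIF4 asked whether the photoreceptor occupied the regions that PIF4 bound. By the rule of at least 1 bp, CRY2 and PIF4 shared most CRY2 regions: 4420 of 7320 CRY2 peaks (60.4%, 95% interval 59.3 to 61.5) overlapped a PIF4 peak. At random positions at like distances from genes the overlap was 19.2% ± 0.435 (SD of 1000 placements), so the observed share was 3.14 times higher (permutation p = 0.001, the smallest possible). Conversely, 4044 PIF4 peaks (40.7%) overlapped a CRY2 peak, against 13.2% at random. Random positions were drawn from whole chromosomes and lay near pseudogenes more often than peaks did (584.7 against 54 for PIF4). The ratios to random may therefore be too high. The clock genes CCA1 and LHY, the phytochrome gene PHYB and RGA, a DELLA repressor of gibberellin responses, were among genes where peaks of both proteins overlapped. Across genes, 3713 were bound by both, where 1744 would be shared by chance (odds ratio 6.50, 95% interval 6.11 to 6.91, Fisher's exact p at the floor of 1e-300). Among genes bound by PIF5, a background chosen after seeing the data, the odds ratio of CRY2 and PIF4 binding was 1.07 (Fisher's exact p = 0.657), and among genes not bound by PIF5 it was 4.37 (p at the floor of 1e-300). With genes bound by at least 1 protein as background it was 0.0299, below 1 because few such genes are bound by neither. When the overlap had to cover at least 50% of both peaks, fewer CRY2 peaks were shared, 2436, at 6.57 times random. The ratio rose to 9.92 times random when summits had to lie within 100 bp of each other. Of the overlapping pairs, 46.7% had summits that near.

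CRY2 was compared with PIF5 for the same purpose. Of CRY2 peaks, 2419 (33.0%, 95% interval 32.0 to 34.1) overlapped a PIF5 peak, against 7.23% ± 0.317 (SD) at random, a ratio of 4.57 (permutation p = 0.001, the smallest possible). In the other direction 2260 of 3767 PIF5 peaks (60.0%) overlapped a CRY2 peak, against 13.1% at random. The 2 proteins shared 2094 genes, against 720.5 by chance (odds ratio 9.13, 95% interval 8.44 to 9.89, p at the floor of 1e-300). These genes included BRI1, the brassinosteroid receptor, and the auxin response gene IAA2. With genes bound by at least 1 protein as background the odds ratio was 1.40, and with genes bound by PIF4 3.18. With summits within 100 bp the peak overlap was 15.3 times random, and 49.3% of the overlapping pairs had summits that near.

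PIF4 and PIF5 were compared to see how far their regions coincided. Nearly every PIF5 region was also a PIF4 region: 3631 of 3767 PIF5 peaks (96.4%, 95% interval 95.7 to 96.9) overlapped a PIF4 peak, against 23.0% at random. The reverse overlap was 3483 of 9925 PIF4 peaks (35.1%), against 8.80% at random, a ratio of 3.99 (permutation p = 0.001, the smallest possible). PIF5 was bound at 3050 genes that PIF4 also bound, which was 93.5% of its genes (odds ratio 57.4, 95% interval 49.8 to 66.2, p at the floor of 1e-300). Both proteins had strong peaks at the auxin biosynthesis gene YUC8 (PIF4 fold enrichment 5.32, PIF5 4.49), at PIF6 (5.34 and 5.80) and at PHYB (4.55 and 6.08). The overlap depended on the strength of the PIF4 peak, from 5.44% in the weakest 10% of PIF4 peaks to 95.4% in the strongest 10%. With genes bound by at least 1 protein as background the odds ratio was 6.58, and with genes bound by CRY2 18.6.

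**Figure D1:**
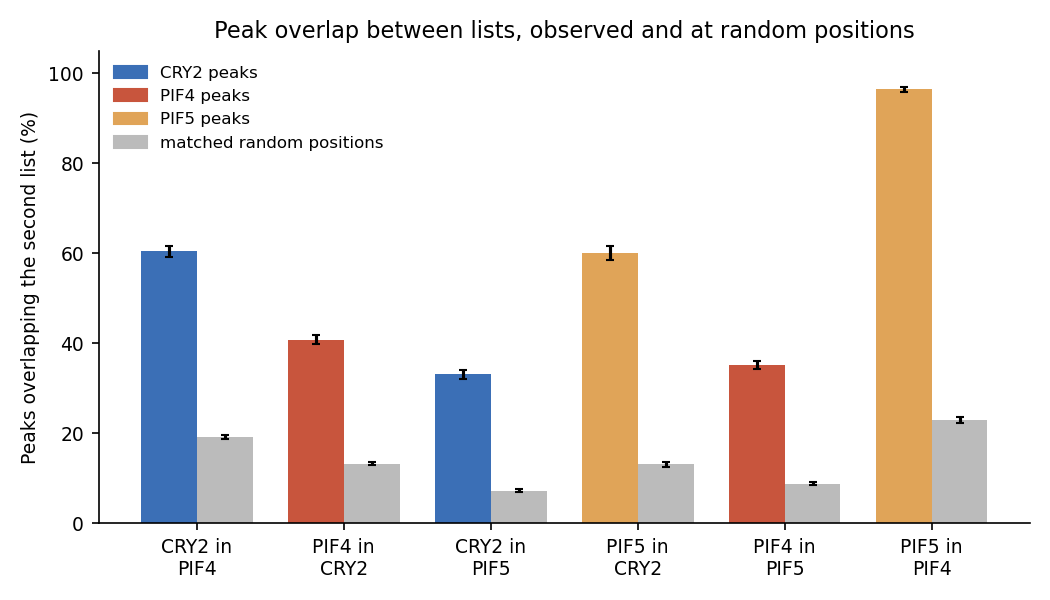
Share of peaks of each list (in %) that overlapped a peak of the second list, observed (coloured bars, 95% Wilson intervals) and at matched random positions (grey bars, mean and SD of 1000 placements). Every observed share lay above its random share, from 33.0% against 7.23% for CRY2 in PIF5 to 96.4% against 23.0% for PIF5 in PIF4.

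CRY2 was found more often at regions common to both PIFs than at regions of PIF4 alone. Merging the lists gave 12738 regions, of which 2123 (16.7%) held all 3 proteins, 1302 both PIFs without CRY2, 1845 CRY2 with PIF4 and 79 CRY2 with PIF5. Of merged PIF regions bound by both PIFs, 2128 of 3430 (62.0%, 95% interval 60.4 to 63.7) overlapped a CRY2 peak, against 1980 of 6578 (30.1%, 29.0 to 31.2) bound by 1 PIF (odds ratio 3.80, 95% interval 3.48 to 4.14, Fisher's exact p = 1.9e-208). The odds ratio was 1.95 with lists of equal size and 2.37 with summits within 100 bp. Stronger PIF4 peaks overlapped PIF5 more often, and CRY2 overlapped 34.5% of the weakest and 57.2% of the strongest 10% of PIF4 peaks. Merged regions were not matched on width. The odds ratios therefore do not separate binding by both PIFs from the strength of PIF4 peaks or the width of regions. Nearly all regions of 1 PIF were PIF4 regions, which held CRY2 in 29.4% of 6442 cases, whereas regions of PIF5 without PIF4 held it in 63.2% of 136 (95% interval 54.9 to 70.9), no less than regions of both PIFs.

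At shared regions the fold enrichment of CRY2 peaks followed that of PIF peaks only weakly. Across overlapping peaks, Spearman's rho of fold enrichment was 0.132 for CRY2 and PIF4 (4420 peaks), 0.153 for CRY2 and PIF5 (2419) and 0.568 for PIF4 and PIF5 (3483). Each had a permutation p of 1e-05, the smallest possible, also after adjustment over the 3 pairs, and peaks are not independent replicates. The median -log10 p of peaks was 6.24 for CRY2, 31.3 for PIF4 and 17.5 for PIF5. Without a spread between replicates, how far measurement error lowers the CRY2 correlations is unknown. PIF4 and PIF5 summits lay a median of 31 bp apart, while CRY2 summits lay 111 bp from PIF4 and 103 bp from PIF5 summits. XTH22, a cell wall xyloglucan enzyme named TCH4 in the gene table, had a CRY2 peak of 6.56 beside a PIF4 peak of 1.78. Within each list, shared peaks were the stronger ones: the median fold enrichment was 2.34 against 2.22 for CRY2 peaks with and without a PIF, 2.66 against 2.36 for PIF4 with and without CRY2, and 2.45 against 2.34 for PIF5 (permutation p = 1e-05 in each, the smallest possible).

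CRY2 and the PIFs differed in where they lay relative to genes. CRY2 summits were inside genes in 59.4% of cases (95% interval 58.3 to 60.5), slightly above the 54.2% of random positions, whereas PIF4 summits were inside genes in 32.9% (32.0 to 33.9) and PIF5 summits in 35.6% (34.1 to 37.1), below random. Outside genes but within 1 kb of a gene edge lay 31.5% of CRY2, 49.2% of PIF4 and 48.3% of PIF5 summits, against 20.4% at random (permutation p = 0.001 for each share, the smallest possible). These random positions came from whole chromosomes, including regions with few peaks. With the gene table shifted by 10000 bp, 22.3% of CRY2 summits lay in such flanks. The small CRY2 excess inside genes may therefore come from the choice of random positions. The 2791 CRY2 peaks without a PIF peak were inside genes in 72.8% of cases, and the 4529 with a PIF peak in 51.1% (odds ratio 2.56, 95% interval 2.31 to 2.84, Fisher's exact p = 4.9e-77). This contrast was chosen after the data were seen, and because PIF peaks lie mostly outside genes, dividing CRY2 peaks by PIF overlap itself separates them by location. At EXO, a gene linked to brassinosteroid-promoted growth, the strongest CRY2 summit was inside the gene and the strongest PIF4 and PIF5 summits outside it. That CRY2 peak also overlapped PIF4 and PIF5 peaks, and those outer PIF4 and PIF5 peaks overlapped a CRY2 peak, so the proteins were not separated there.

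**Figure D2:**
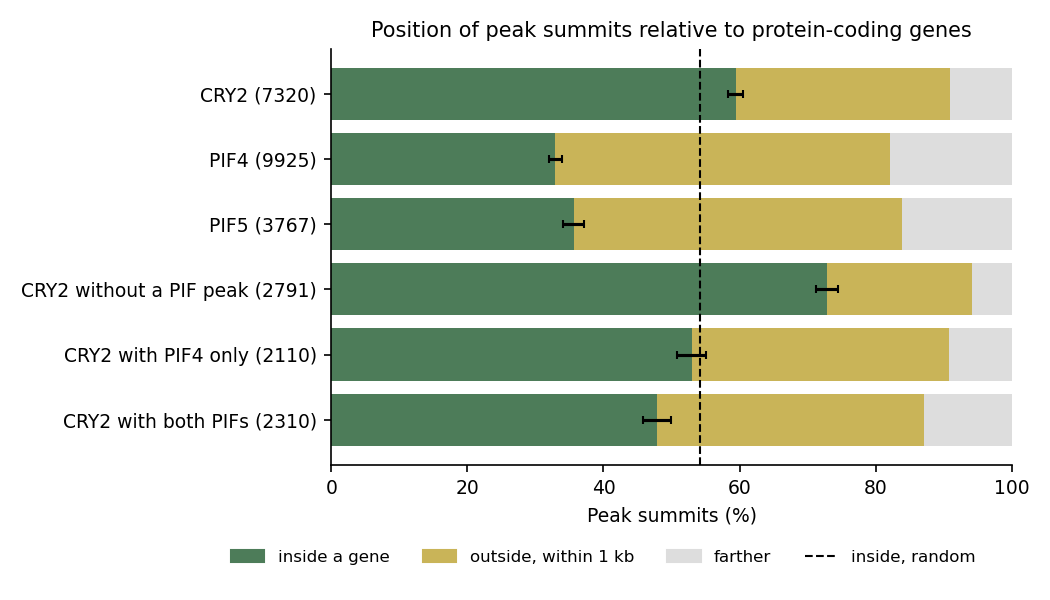
Share of peak summits (in %) inside protein-coding genes, outside but within 1 kb of a gene edge, and farther away, for the 3 lists and for CRY2 peaks by their overlap with PIF peaks (number of peaks in parentheses). Black bars are 95% intervals of the share inside genes, and the dashed line is the share at random positions (54.2%).

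**Figure D3:**
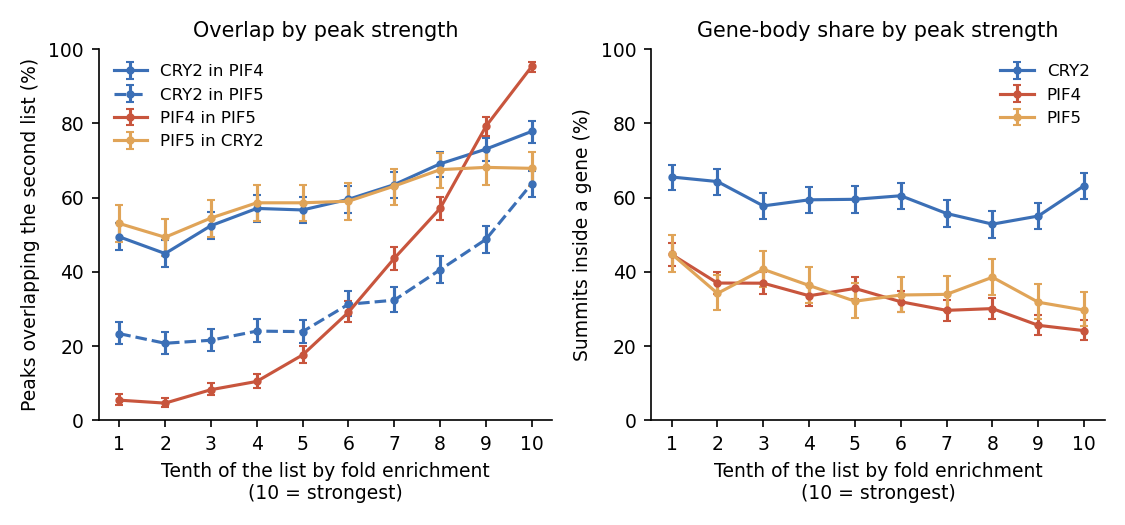
Overlap with a second list (left, %) and share of summits inside genes (right, %) in 10 equal bins of each list, ranked by fold enrichment, with 95% Wilson intervals. PIF4 overlap with PIF5 rose from 5.44% to 95.4%, and the weakest and strongest 10% of CRY2 peaks were inside genes in 65.6% and 63.3% of cases.

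Genes bound by all 3 proteins numbered 1961, 9.46 times the 207.3 that independent binding of the 3 would give. This ratio also holds the overlap of the 2 PIFs, since PIF4 was bound at 93.5% of PIF5 genes. For 1 pair at a time, shared genes were 2.13 times the independent count for CRY2 with PIF4, 2.91 for CRY2 with PIF5 and 3.25 for the PIFs. In 95.4% of the 1961 genes a CRY2 peak overlapped a PIF peak. The 10 genes with the best mean rank were EXO, AT3G15220, BRG3, LCR32, OBP4, AT5G60680, SHOT1, BME3, AT5G08139 and AT1G71520. They include OBP4, a DOF transcription factor, BME3, a GATA factor of seed germination, and BRG3, a RING-type ubiquitin ligase. EXO (AT4G08950) had a CRY2 peak of 6.04 at chromosome 4, 5739980 to 5741464, inside the gene, and PIF4 and PIF5 peaks of 4.98 and 4.88 outside it (PIF4 at 5738543 to 5739343). OBP4 (AT5G60850) had peaks of 4.31, 4.88 and 4.31 for CRY2, PIF4 and PIF5, with the CRY2 peak at chromosome 5, 24481960 to 24483027. AT3G15220 had 3.45, 4.99 and 6.23, with CRY2 at chromosome 3, 5123953 to 5126444. Across the 10 genes, CRY2 peaks ranged from 3.25 to 6.04, PIF4 from 4.50 to 4.99 and PIF5 from 4.31 to 6.23. The count of genes was 664 when only summits outside genes within 1 kb counted, 791 with the upper 50% of each list, 1132 with lists of equal size and 3348 with every gene within 1 kb of a peak. Of the 10 named genes, 3 were bound by all 3 proteins when only summits outside genes counted.

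CRY2 alone was bound at 2216 genes, PIF4 alone at 3094 and PIF5 alone at 79. The strongest CRY2 peaks at such genes lay inside AT1G79485 (6.10), AT1G01725 (4.92), AT2G30740 (4.77), MSRB2 (4.48), a methionine sulfoxide reductase, and AT5G52050 (4.44). Those for PIF4 were at AT1G72460 (4.51), RPD1 (4.49), MTSSB (4.33), ACP1 (4.25), an acyl carrier protein, and MYB47 (4.21), a MYB factor. PIF5 had GH9C3 (3.89), AT1G72910 (3.51), AT1G03610 (3.37), AT4G33490 (3.06) and AT1G27300 (2.93). Among these genes, the peaks of AT2G30740, AT5G52050, MYB47 and AT1G72910 overlapped no peak of another protein, and at the others, overlapping peaks were assigned to different neighbouring genes. MTSSB and GH9C3 held the PIF4 and PIF5 peaks of 1 region, chromosome 4 from 6752648 to 6753487 for PIF4. A peak overlapping one of another protein was found at 57 of the 79 PIF5 genes (72.2%), 16.3% of the CRY2 genes and 6.88% of the PIF4 genes.

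The 14 gene lists were tested to see which processes the bound genes belonged to, and 29 of 42 tests were called: 9 for CRY2, 10 for PIF4 and 10 for PIF5. All calls were above the share of all genes. They included the housekeeping control for each protein, with 52.9% of its members bound by CRY2, 70.6% by PIF4 and 52.9% by PIF5. A call alone therefore does not set a process apart from housekeeping genes. Of the 29, 15 held under every alternative, 5 for CRY2 and PIF4 and 4 for PIF5, whose list is the smallest and so is unchanged with lists of equal size: brassinosteroid and clock genes for CRY2, shade, auxin, cell wall, light signalling, clock, ethylene and housekeeping genes for PIF4, and shade, auxin, brassinosteroid, clock, ethylene and housekeeping genes for PIF5. The others were lost under at least 1, with 17 tests called when only summits outside genes within 1 kb counted and 19 against random genes of like length. Each p below was adjusted over the 42 tests and came from Fisher's exact test, or from permutation where genes of like length are named.

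Genes of shade avoidance and known PIF targets were among the most densely bound. PIF4 and PIF5 were each bound at 12 of 14 members (adjusted exact p = 8.3e-05 and 1.2e-08), and CRY2 at 8 of 14 (0.00972, 2.59 times the share of all genes, and 2.19 times and 0.0546 against genes of like length). Known PIF targets were listed as such, so binding by the PIFs is favoured by the choice of members. All 3 proteins were at 8 members, among them the homeobox genes ATHB2 (AT4G16780; CRY2 2.13, PIF4 3.75, PIF5 2.53), HAT2 (2.24, 3.91 and 2.90) and HAT3 (2.45, 3.09 and 2.60), and PAR2 (2.59, 2.76 and 2.1), an atypical bHLH gene. At HAT3 the strongest CRY2 peak overlapped no PIF peak, but the strongest PIF4 and PIF5 peaks overlapped another CRY2 peak. The remaining 2 members, PIL1 and HFR1, bHLH genes induced by shade, counted as unbound by the PIFs because their PIF peaks were assigned to a neighbouring gene. PIL1 (AT2G46970) lay within 1 kb of the strongest PIF5 peak of the list (7.21, chromosome 2, 19298593 to 19299494) and of a PIF4 peak of 5.29, without a CRY2 peak at that distance. HFR1 lay within 1 kb of peaks of 5.18 for PIF4, 5.79 for PIF5 and 2.41 for CRY2, both genes being singled out after their values were seen. PAR1, ATHB4, ST2A and PRE1 were bound by both PIFs without CRY2.

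The genes of the auxin list were bound by the PIFs far more than by CRY2. PIF4 was at 25 of 33 members (adjusted exact p = 2.6e-07), PIF5 at 18 (4.0e-08) and CRY2 at 10 (0.322, not called). Of members bound by CRY2 or PIF4 but not both, 15 were bound by PIF4 and 0 by CRY2 (Fisher's exact test, adjusted p = 0.0373 against all other such genes), and of members bound by CRY2 or PIF5 but not both, 10 were bound by PIF5 and 2 by CRY2 (6.3e-04). Neighbouring SAUR genes counted as separate members, so members are not independent. Whether the choice of members favours the PIFs was not tested. The genes bound by both PIFs without CRY2 included YUC9, which acts in auxin synthesis, the response genes IAA3, IAA7, IAA14 and IAA19, and the growth genes SAUR19, SAUR22 and SAUR24. A CRY2 peak of 2.64 lay within 1 kb of IAA19 but was assigned to its neighbour, as seen after the values were known. Members bound by all 3 were YUC8, IAA2, the auxin transporters PIN3 and PIN7, GH3.3, GH3.5, GH3.6 and ARF6. At YUC8 the only CRY2 peak (2.13) lay inside the gene and overlapped no PIF peak. IAA2 (AT3G23030) had peaks of 2.99 for CRY2, 4.72 for PIF4 and 6.06 for PIF5 with overlapping positions, CRY2 at chromosome 3, 8180527 to 8182153. PIN3 had 2.30, 4.03 and 3.19, and PIN7 2.18, 3.53 and 2.48.

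Cell wall expansion genes, which encode expansins and xyloglucan enzymes, were bound by PIF4 at 17 of 19 members (adjusted exact p = 4.0e-07), by CRY2 at 9 (0.0337) and by PIF5 at 6 (0.0312), the last 2 calls being lost against genes of like length (0.0988 and 0.188), where the ratio went from 2.14 to 1.87 for CRY2 and from 2.66 to 1.99 for PIF5. With lists of equal size the counts were 6 for PIF4, 6 for PIF5 and 5 for CRY2. In the full lists, members bound by 1 of 2 proteins were 1 for CRY2 and 9 for PIF4 (adjusted exact p = 0.439). For the other pair they were 11 for PIF4 and 0 for PIF5 (adjusted exact p = 1). Neither split was called as different from that of all other such genes. With summits outside genes only, the CRY2 share fell below that of all genes (ratio 0.648, 1 member, adjusted exact p = 1). XTH22 (AT5G57560) had a CRY2 peak of 6.56 at chromosome 5, 23306902 to 23308277, inside the gene, with overlapping PIF4 and PIF5 peaks of 1.78 and 3.29. XTH18 (2.67, 3.05 and 2.64) and EXPA6 (2.05, 3.3 and 2.26) were also bound by all 3. At both, the strongest CRY2 summit was inside the gene and the strongest PIF summits outside, but the CRY2 peak at EXPA6 overlapped a PIF4 peak. XTH15 was bound by PIF4 (4.30) and PIF5 (3.10) only.

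Brassinosteroid genes were bound by all 3 proteins at 10 of 15 members. CRY2 was at 11 (adjusted exact p = 1.6e-04), PIF4 at 12 (2.0e-04) and PIF5 at 12 (3.5e-08). BRI1 had peaks of 3.04, 3.81 and 3.59 for CRY2, PIF4 and PIF5, the kinase gene BIN2 1.95, 3.86 and 4.54, the transcription factor gene BZR1 2.39, 2.39 and 2.21, and the biosynthesis gene DWF4 2.36, 4.39 and 4.67. The PIF4 call was lost when only summits outside genes within 1 kb counted (4 members, 1.59 times the share of all genes against 2.78, adjusted exact p = 0.449).

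Gibberellin genes were bound by CRY2 at 10 of 16 members (adjusted exact p = 0.00135), by PIF4 at 10 (0.0100) and by PIF5 at 6 (0.0131). All 3 were at the DELLA genes GAI (2.47, 3.27 and 2.03) and RGA (2.61, 5.00 and 4.60), the receptor genes GID1A (2.64, 4.50 and 3.82), GID1B and GID1C, and the catabolic gene GA2OX6 (3.16, 3.72 and 3.14). Against genes of like length the PIF4 and PIF5 calls were lost (0.239 and 0.172), with ratios of 1.47 and 2.04 in place of 2.17 and 3.15. With summits outside genes only, the CRY2 share fell below that of all genes (ratio 0.769, 1 member, adjusted exact p = 1).

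Photoreceptor genes were bound by CRY2 at 7 of 12 members (adjusted exact p = 0.0128, 2.64 times the share of all genes, and 2.1 times and 0.0906 against genes of like length), by PIF4 at 7 (0.0649) and by PIF5 at 4 (0.0630), the last 2 not called. With the upper 50% of each list PIF4 and PIF5 were called (adjusted exact p = 0.0106 and 0.00999) and CRY2 was not (0.0597), and with lists of equal size PIF4 was called (6 members, 0.0039) and CRY2 was not (2 members, 0.700). PHYB had overlapping peaks of 2.39, 4.55 and 6.08, with CRY2 at chromosome 2, 8139154 to 8140372. PHYA had 2.07, 3.79 and 3.36, and the phototropin gene PHOT1 2.30, 5.14 and 3.71, with the strongest CRY2 and PIF peaks at different positions. The CRY2 gene itself carried CRY2 peaks of up to 3.78 inside the gene, in a line that also carries CRY2 as a transgene. This gene is among the 7 members counted for CRY2.

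Light signalling genes were bound by PIF4 at 21 of 36 members (adjusted exact p = 8.9e-04), by CRY2 at 14 (0.0369) and by PIF5 at 10 (0.0131). Against genes of like length the CRY2 and PIF5 values were 0.119 and 0.0825, with ratios of 1.58 and 1.98 in place of 1.76 and 2.34. PIF6 (2.86, 5.34 and 5.80 for CRY2, PIF4 and PIF5), SPA1 (3.33, 3.62 and 2.95), which encodes a partner of the COP1 ubiquitin ligase, and BBX21 (2.41, 3.89 and 3.33) were bound by all 3. PIF5 was bound at its own gene (2.44), in a line that also carries PIF5 as a transgene, and CRY2 (2.93) and PIF4 (2.24) shared a different region there. The PIF5 gene is among the 10 members counted for PIF5, and the PIF4 gene among the 21 counted for PIF4.

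Circadian clock genes were bound by PIF4 at all 21 members (adjusted exact p = 1.8e-10), by PIF5 at 13 (4.5e-07) and by CRY2 at 12 (0.00127). All 3 proteins were at 9: CCA1, LHY, TOC1, PRR7, PRR5, LUX, GI, CHE and CDF1. CCA1 had peaks of 3.04, 2.98 and 2.87 for CRY2, PIF4 and PIF5, LHY 3.06, 3.99 and 2.65, TOC1 2.48, 2.43 and 2.61, and PRR7 3.11, 2.97 and 2.46. At each of these 4 genes the 3 peaks overlapped, with CRY2 at CCA1 on chromosome 2 from 19245052 to 19245713.

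Ethylene genes were bound by PIF4 at 11 of 13 members (adjusted exact p = 1.8e-04), by PIF5 at 7 (8.9e-04) and by CRY2 at 5 (0.207, not called). CRY2 was called with the upper 50% of each list (adjusted exact p = 0.0210) and with lists of equal size (0.0260). The ethylene synthesis genes ACS2 (2.64, 2.71 and 2.08) and ACS6 (2.76, 1.93 and 3.69), the transcription factor gene EIL1 (2.34, 4.24 and 3.41) and the F-box gene EBF1 (3.22, 3.14 and 3.05) were bound by all 3. Stress response genes were bound by CRY2 at 8 of 11 members (0.00127, 3.29 times the share of all genes, and with summits outside genes only 3.36 times with 3 members and 0.113), by PIF5 at 4 (0.0478, 3.06 times, and against genes of like length 3.27 times and 0.0906) and by PIF4 at 6 (0.117, not called). With every gene within 1 kb of a peak counted, PIF4 was at 10, CRY2 at 9 and PIF5 at 7 members, all called (adjusted exact p = 0.0029). The zinc finger gene ZAT10 (AT1G27730) had the strongest CRY2 peak of the list, 7.87 at chromosome 1, 9647580 to 9649732, with PIF4 and PIF5 peaks of 3.07 and 3.55. ZAT12 had 4.16, 3.39 and 3.25, WRKY40 3.56, 3.35 and 2.80, and HSP101 2.45 for CRY2 and 2.44 for PIF4.

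Photosynthesis and chlorophyll genes were bound by PIF4 at 15 of 27 members (adjusted exact p = 0.00972), by CRY2 at 9 (0.198) and by PIF5 at 4 (0.597). The PIF4 call was lost with lists of equal size, where its share fell below that of all genes (ratio 0.910, 3 members, adjusted exact p = 1). With summits outside genes only, CRY2 and PIF5 were at 0 members, against ratios of 1.51 and 1.25 with all summits. LHCB1.3 (2.42, 2.26 and 3.14), HEMA1 (2.41, 2.22 and 2.13) and PSY (2.36, 3.69 and 2.15) were bound by all 3, and LHCA1 by CRY2 (2.12) and PIF4 (1.89). The strongest CRY2 peaks at PSY and LHCA1 overlapped no PIF peak, although the strongest PIF4 peaks there overlapped another CRY2 peak. Flowering genes were not called for any protein, with 2, 4 and 0 of 8 members bound by CRY2, PIF4 and PIF5 (0.709, 0.271 and 0.638), and the CRY2 ratio of 1.13 fell below 1 under 4 of 5 alternatives. FT and AP1 carried PIF4 peaks of 3.27 and 2.57, and TSF (2.11 and 3.81) and SVP (2.13 and 2.08) peaks of CRY2 and PIF4.

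The 2 control lists behaved differently from each other. Housekeeping genes were bound at 9 of 17 members by CRY2 (adjusted exact p = 0.0100, 2.4 times the share of all genes, and 2.04 times and 0.0548 against genes of like length), 12 by PIF4 (0.00120) and 9 by PIF5 (1.8e-04), and 5 by all 3. These 5 were ACT2 (2.87, 3.75 and 2.83), ACT7 (2.93, 2.65 and 2.57), UBQ10 (2.84, 2.14 and 2.86), TUB2 (2.59, 2.34 and 2.52) and UBQ3. The CRY2 count includes UBQ10, whose promoter drives the CRY2 transgene. Seed and floral genes were bound at 1 of 18 members by CRY2, 2 by PIF4 and 1 by PIF5 (0.185, 0.153 and 0.714). Those bound were PI by CRY2 (2.2), SEP3 (2.05) and LEC2 (2.45) by PIF4, and OLEO1 by PIF5 (2.44). With every gene within 1 kb of a peak counted, PIF4 was at 5, PIF5 at 2 and CRY2 at 1 (adjusted exact p = 0.445, 0.775 and 0.0240, the last below all genes). PIF4 peaks within 1 kb of CRB (3.87), OLEO1 (2.82), EM6 (2.45) and PI (3.29) had been assigned to neighbouring genes, as seen after the values were known.

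**Figure D4:**
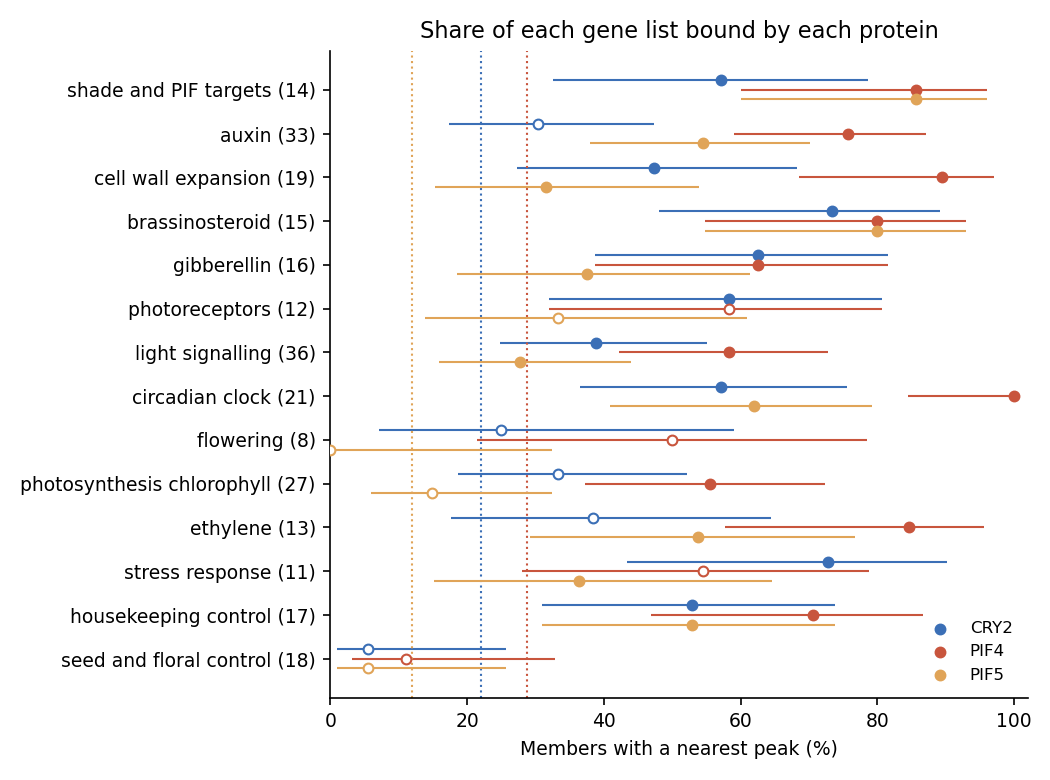
Share of the members of each gene list (number in parentheses) with a nearest peak of CRY2, PIF4 or PIF5 (in %), with 95% Wilson intervals; filled points had an adjusted p below 0.05 and dotted lines are the shares of all genes (22.1, 28.8 and 11.9%). PIF4 reached 21 of 21 clock genes, and seed and floral genes lay below the shares of all genes.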

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

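The tests on housekeeping genes, on gene bodies by peak strength and over the whole peak, on the precipitation protocols and on PIF4 peaks by strength, the contrasts of gene-body shares, the tests of genes bound by 1 of 2 proteins and the counts near non-coding genes were chosen after the results were seen.

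CRY2 peaks overlapped PIF4 and PIF5 peaks more often than matched random positions did. With each list reduced to its 3767 highest-ranked peaks, the CRY2 overlap with PIF4 was 4.48 times random (39.8% against 8.90%). For CRY2 this cut lies near the list's median -log10 p of 6.24, so only the weaker CRY2 peaks were removed. In the full lists, 49.5% of the weakest 10% of CRY2 peaks by fold enrichment overlapped PIF4, and 77.9% of the strongest 10%. These values argue against weak peaks near the calling threshold as the whole cause. Accessible chromatin of active genes stays open and may contribute: 5 of 17 housekeeping genes (29.4%) were bound by all 3 proteins, against 7.13% of other genes (Fisher's exact p = 0.00554). The 5 include UBQ10, whose promoter drives the CRY2 transgene. Regions that enrich in any anti-FLAG precipitation also stay open, since CRY2 peaks near tRNA and snRNA genes, where CRY2 and PIF4 summits were in excess and PIF5 summits were not, overlapped a PIF peak in 59.3% of 91 cases and other CRY2 peaks in 61.9% of 7229 (Fisher's exact p = 0.664), and no precipitation from untagged plants was used here. No biological explanation was tested, because all libraries came from low blue light and from lines with a single tagged protein.

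CRY2 summits lay inside genes more often than PIF summits, in 59.4% of cases against 32.9% for PIF4 and 35.6% for PIF5. Among CRY2 peaks without PIF4 and PIF4 peaks without CRY2 the shares were 73.3% and 29.9% (odds ratio 6.41, 95% interval 5.81 to 7.09, Fisher's exact p at the floor of 1e-300), and for CRY2 and PIF5 64.3% and 28.9% (odds ratio 4.42, 3.90 to 5.02, p = 3.3e-130), but leaving out shared peaks itself moves these shares apart when PIF peaks lie mostly outside genes. Weak peaks are argued against as the whole cause by the strongest 10% of CRY2 peaks, which lay inside genes in 63.3% of cases (95% interval 59.7 to 66.7) against 32.9% of all PIF4 peaks and 24.2% of the strongest 10% of PIF4 peaks. The CRY2 share did not rise steadily with strength. It was 65.6% in the weakest 10% and lowest, at 52.9%, in bin 8 of 10. A shift of CRY2 summits within their peaks is argued against as the whole cause by whole peaks, which lay inside genes in 29.5% of CRY2 and 8.63% of PIF4 cases (odds ratio 3.19 over 10 strata of equal width, 95% interval 2.9 to 3.5), but a shift of whole CRY2 peaks was not tested. Dual cross-linking and the larger amount of material cannot be told apart from the protein, since 0 CRY2 libraries were made as the PIF libraries were, and a difference between the proteins themselves stays open as untested.

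PIF4 had more peaks and bound genes than PIF5. The overlap of PIF4 peaks with PIF5 peaks was 95.4% in the strongest 10% of PIF4 peaks and 5.44% in the weakest 10%, which is consistent with a shorter PIF5 list that lacks the weaker PIF4 regions, although the lowest -log10 p was 10.3 for PIF5 and 13.4 for PIF4 and the lowest fold enrichment 1.86 and 1.65, so the 2 thresholds cannot be ordered. For cell wall and SAUR genes, 37 of 99 were bound by PIF4 alone of the 2 proteins and 1 by PIF5 alone. With PIF4 reduced to as many peaks as PIF5 these were 14 and 5 (exact binomial p = 0.0636), too few genes to show an even split or an uneven one. PIF4 had 3 FLAG libraries and PIF5 had 2, depth is unknown, and a difference between the proteins stays open as untested.

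Auxin genes differed between CRY2 and the PIFs among genes bound by 1 protein of a pair, with 0 bound by CRY2 and 15 by PIF4 (Fisher's exact test, adjusted p = 0.0373) and 2 bound by CRY2 and 10 by PIF5 (adjusted p = 6.3e-04). Whether the choice of auxin genes favours the PIFs was not tested, and neighbouring SAUR genes counted separately. Shade and PIF target genes differed between CRY2 and PIF5 in the same test, with 0 bound by CRY2 and 4 by PIF5 (adjusted exact p = 0.0373), but that list includes known PIF targets, so its choice of members favours PIF5. Outside the protein-coding genes, 73 CRY2 and 81 PIF4 summits lay within 200 bp of a tRNA gene, against means of 30.8 and 53.3 in random draws (adjusted permutation p = 0.004 and 0.0072), while PIF5 had 20 against 19.6 (adjusted permutation p = 1). Within 200 bp of snRNA genes lay 18 CRY2 and 13 PIF4 summits, against 4.17 and 6.93 (adjusted permutation p = 0.004 and 0.0437), and PIF5 had 2 against 2.46 (adjusted permutation p = 1). These draws came from whole chromosomes, so the excesses may be too high.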

How the results depend on the processing

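The tests with a background set by the third protein, the gene counts from lists of equal size, the gene-body shares, the regression on gene length and the removal of peaks near tRNA and snRNA genes were chosen after seeing the data. Of 91 alternatives to the main results, 83 kept the direction and the side of the threshold, or for counts stayed within 1.5 times. The peak overlaps did so under all 8 alternatives each, at 3.07 to 9.92 times random for CRY2 and PIF4, 4.63 to 15.3 for CRY2 and PIF5 and 4.02 to 23.6 for PIF4 and PIF5. So did gene overlaps of CRY2 with PIF5 (odds ratio 1.40 to 13.0) and of PIF4 with PIF5 (6.58 to 84.8), CRY2 at regions of both PIFs (1.95 to 2.98), the gene-flank and gene-body shares, the strength of shared peaks and the rank correlations. For the peak overlaps, every alternative drew random positions from whole chromosomes, also where peaks in gene-poor pericentromeric regions were left out. None therefore tested whether random positions in regions with few peaks raise the ratios. The gene-flank and gene-body shares likewise used uniform positions on whole chromosomes under every alternative.

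The gene overlap of CRY2 and PIF4 reversed to an odds ratio of 0.0299 when the background was the genes bound by at least 1 protein, which follows from the construction, since few of those genes are bound by neither. It lost its call among genes bound by PIF5 (odds ratio 1.07, Fisher's exact p = 0.657). Few genes in that background lacked PIF4, 133 with CRY2 and 79 without it. At 57 of these 79 the PIF5 peak overlapped a peak of another protein assigned to a different gene, so gene assignment may contribute. The cause was not tested. Genes bound by all 3 proteins went from 1961 to 664 with summits outside genes within 1 kb only, 791 with the upper 50% of each list, 1132 with lists of equal size and 3348 with every gene within 1 kb of a peak, each of which changes how many peaks or genes count by construction. Called gene list tests went from 29 to 17 with summits outside genes only and to 19 against random genes matched on length; the cause was not tested. For single lists, bound shares fell below those of all genes for cell wall (ratio 0.648) and gibberellin genes (0.769) in CRY2 with summits outside genes only, and for photosynthesis genes in PIF4 (0.910) with lists of equal size, with adjusted exact p = 1 in each; the cause was not tested. Among lists without a call, the ratio fell from above 1 for photosynthesis genes in CRY2 (1.51 to 0) and PIF5 (1.25 to 0) and for flowering genes in CRY2 (1.13 to 0) with summits outside genes only. It also fell for photosynthesis genes in PIF5 to 0.623 with every gene within 1 kb of a peak and to 0.591 with the upper 50% of each list. Flowering genes in CRY2 had 0 with the upper 50% and with lists of equal size, and 0.860 against genes matched on length. Of 200 alternatives to single gene lists and named genes, 150 kept their direction and call, 31 lost a call, 7 gained one, 11 reversed and 1 moved.

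Settings intended for G-box and PBE-box elements were not run, since these need the genome sequence. No paired analysis was possible because each list pools its replicates, and for the same reason no replicate was left out. The depth of the libraries is unknown, so a gene without a peak was not detected at that depth rather than shown to be unbound.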

Other observations

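The counts by gene family, of peaks near non-coding genes and of the strongest peaks were chosen after the data were seen. Gene families, taken as symbols with a common stem and at least 15 members, gave 303 tests over 101 families, of which 3 were above the share of all genes for CRY2, 13 for PIF4 and 7 for PIF5, and 1, 3 and 1 below it. WRKY genes, transcription factors of defence and stress, were bound at 27 of 72 members by CRY2 (adjusted exact p = 0.0367), 41 by PIF4 (6.5e-05) and 30 by PIF5 (4.9e-08), with 17 bound by all 3. ERD genes, named for early responses to dehydration, were bound at 12, 14 and 11 of 17 members (8.1e-04, 2.7e-04 and 6.2e-05). PIF4 and PIF5 were at 21 and 14 of 30 homeobox genes named ATHB (1.7e-04 and 1.5e-04) and at 18 and 13 of 26 CIPK protein kinase genes (7.5e-04 and 1.5e-04). PIF4 was at 39 of 80 SAUR genes (0.00391) and 18 of 30 BBX genes (0.00698). LCR genes, which encode small cysteine-rich proteins, were bound less than other genes, at 3, 10 and 2 of 84 members (1.7e-04, 0.00698 and 0.0407). None of these families was tested under the alternatives.

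Most of the strongest CRY2 peaks lay inside genes and overlapped PIF peaks. Of the 20 strongest, 19 were inside genes, 18 overlapped PIF4 and 19 overlapped PIF5. After ZAT10 (7.87) came EXL2 (7.73), an EXO-like gene, RAP2.4 (7.01), an ethylene response factor gene, J11 (6.86), AT1G05136 (6.61), XTH22 (6.56), HSPRO2 (6.45) and ERF4 (6.14), all chosen after their values were seen. Of the 20 strongest PIF4 peaks 1 was inside a gene, all 20 overlapped PIF5 and 11 overlapped CRY2. Of the 20 strongest PIF5 peaks 4 were inside genes, all 20 overlapped PIF4 and 15 overlapped CRY2. Near lncRNA genes lay 381 CRY2, 500 PIF4 and 206 PIF5 summits, against 211.9, 334.3 and 125.8 in random draws (adjusted permutation p = 0.004 in each). Near pseudogenes lay 78, 54 and 18 summits, against 239, 584.7 and 199.2 (0.004 in each). All these draws came from whole chromosomes, so the ratios to random near non-coding genes may depend on that choice. Near snoRNA genes PIF4 and PIF5 had 2 and 0 summits, against 12.2 and 4.72 (adjusted permutation p = 0.004 and 0.027), and CRY2 had 11 against 7.1 (0.262). Near miRNA genes they had 10 and 1, against 20 and 7.45 (adjusted permutation p = 0.0305 and 0.0131), and CRY2 had 10 against 10.8 (1).

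The loci used in the transgenes were all bound by CRY2 and PIF4. CRY2 peaks were 3.78 at the CRY2 gene, 2.76 at PIF4, 2.93 at PIF5 and 2.84 at UBQ10. PIF4 peaks at the same genes were 2.18, 3.21, 2.24 and 2.14. PIF5 peaks were 2.44 at PIF5 and 2.86 at UBQ10, with no peak at the CRY2 and PIF4 genes. Each line also carries its own protein as a transgene.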
